A study of Mus musculus with 4 samples.

How the data were processed

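Single cells of mouse limb buds at stage E12.5 were measured with 10x Genomics 3' gene expression libraries, 2 from Mettl14 cHet and 2 from Mettl14 cKO embryos. The labels call the 2 libraries of each group biological replicates and do not say how many embryos went into each, which Cre driver was used or which exons are floxed. Per the submitters' processing notes and per the file headers, reads were processed with Cell Ranger 7.1 against mm10, and the deposited values are raw UMI counts per gene and cell barcode, for barcodes called as cells. Whether intronic reads were counted, and the annotation release, are not given in the sources used here. Each library held 32285 features, of which 78 symbols were used more than once and kept apart by gene identifier. Gene positions and exon counts came from GENCODE vM21, which shares the GRCm38 (mm10) build and gave a position for 99.6% of features.

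Tests, thresholds, gene lists, markers and the rule for naming genes were fixed before the data were examined. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes (54945 of 58971). Doublets were scored with Scrublet in scanpy 1.11.5 for each library. The automatic threshold was used where it marked between 0.5% and 30% of cells, which held for cKO replicate 2 alone (9.27%). In the other libraries the highest scores were removed at 0.8% per 1000 barcodes (13.02%, 9.03% and 8.75%), leaving 49349 cells. Counts were scaled to 10000 per cell, logged and turned into z-scores within each library, which removes shifts of a whole library before clustering. Clustering used 2000 variable genes without mitochondrially encoded, hemoglobin, sex-linked and cell cycle genes, 30 principal components, 20 neighbours and Leiden (leidenalg 0.10.2) at resolution 1, and gave 28 clusters. A cluster could take a type from 13 fixed sets if at least 3 of its markers were raised (1.5-fold over other cells, in 10% of its cells). Among such types it took the one with most markers among its 10 leading genes, and at a tie the one with most raised markers. A cluster stayed unnamed if it had too few markers, or if its median UMIs lay under 1 in 3 of the other cells' with no marker among its 10 leading genes. Because called genes can move cells between clusters, cells were also clustered with the 9874 genes called in any mesenchymal class left out.

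UMI counts were summed over the cells of each library, for all cells and for each named class with at least 50 cells in every library. cKO was compared with cHet by edgeR 4.0.16 (quasi-likelihood test, TMM factors, genes kept by filterByExpr), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, in R 4.3.3. Every adjusted p in the report without another tool's name is edgeR's for genes and class shares and limma's for gene lists. A further edgeR fit with a term for each library asked which changes differ between chondrogenic-like and mesenchyme-like cells. Class shares were tested on cell counts by edgeR and by an exact permutation test, two-sided, whose smallest p with 2 against 2 libraries is 0.333. For shares of cells with a UMI and for cell cycle phases, cells of the mesenchymal classes were thinned to 4000 UMIs and shallower cells left out. Shares carry 95% exact binomial intervals. 31 fixed gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and again with the correlation estimated from the libraries and with fry.

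Genes named in the report were picked by rule: the 12 largest rises and falls over all cells, 10 of each in the main classes and 3 of each in other classes, among genes past the threshold whose libraries do not overlap and whose mean is at least 10 CPM in a group. Where fewer than 5 genes passed, the 10 with the smallest p were taken, and up to 4 members of each list were named. Predicted genes, ribosomal protein genes and sex-linked genes were left out of the ranking. Mettl14, Mettl3, Gdf5, the Runx genes, Sox9, Col2a1 and Acan were always named, since the labels or series title point to them.

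The alternatives tried were DESeq2 1.42.0, relative log expression factors, no filter on low counts, sums thinned to the smallest library, replicate number as a block, each library left out, stricter cells (2000 UMIs, 1000 genes, 5%), no doublet removal, Leiden resolutions 0.5 and 2, z-scores over all cells and thinning to 2000 UMIs. Chosen after the data were seen were the sums without unnamed clusters or over mesenchymal classes only, the chondrogenic-like class without the cluster led by Papss2, clustering without called genes, shares among named cells and a crossed block for erythroid-like cells. Left out of the gene tests by class, but not of the share tests, were neural crest and glia-like and megakaryocyte-like cells, which were too few, and cells of unnamed clusters.

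The pipeline was tested on simulated data with 200 changed genes, far fewer than the 7390 called over all cells, so its false calls need not carry over. edgeR recovered 59.7%, 64.6% and 97% of genes changed 1.5-fold, 2-fold and 4-fold over all cells with 4 false calls, 53.8%, 71.6% and 93.9% in chondrogenic-like cells with 1, 34.8%, 68.2% and 90.8% in mesenchyme-like cells with 0, and 28.4%, 60.6% and 84.8% of class differences with 8. The planted list, the cartilage matrix genes lowered 2-fold, was found by camera with the preset correlation in all 3 fits. With the estimated correlation its adjusted p was 0.0312 over all cells, 0.123 in chondrogenic-like and 0.0835 in mesenchyme-like cells. With fry it was 0.00182, 0.0575 and 0.0146, and fry also called 1 unchanged list over all cells. The estimated correlation can therefore miss a planted shift in a single class, but over all cells both settings found this one. The simulated genes varied independently of each other and no other list was changed. Whether preset-correlation calls are false where genes vary together was thus not tested. Counts of replicate libraries differed by more than sampling noise (chi-square per degree of freedom 96.3 in cHet and 22.5 in cKO), and the tests use this spread. Summed UMIs per library ran from 108.56 to 238.25 M for all cells and from 13.92 to 46.46 M for chondrogenic-like cells. Figures were drawn with Python 3.11.15.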

Results

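Limb buds of mouse embryos at stage E12.5 were profiled in 4 single-cell RNA libraries. 2 libraries came from embryos with a wild-type and a floxed copy of Mettl14 (cHet, the control) and 2 from embryos with only floxed copies (cKO). METTL14 is the partner of METTL3 in the nuclear complex that writes the RNA mark N6-methyladenosine (m6A). The libraries held 16282 and 11286 cell barcodes in cHet and 10935 and 20468 in cKO, with 321.7, 234.8, 136.7 and 282.1 M UMIs. After filters and doublet removal 13438, 9861, 9033 and 17017 cells stayed, with median UMIs of 15445, 16187, 10344 and 11602. The cKO libraries were therefore the shallower ones, and 26.2% and 15.6% of their cells held under 4000 UMIs against 3.7% and 2.8% in cHet. Fixed markers named most of the 28 clusters as chondrogenic-like, interzone/perichondrium-like, mesenchyme-like, tendon/connective-like, muscle-like, endothelium-like, ectoderm-like, erythroid-like or macrophage-like cells. The labels give no sex, and cHet replicate 2 alone lacked Xist (0.1 against 782.5 to 980.1 counts per M UMIs, CPM) and held Ddx3y (56.7 against at most 0.5 CPM).

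Mettl14 itself was read in every library, at 15.75 and 17.34 CPM in cHet and 13.26 and 14.01 CPM in cKO. The gene (ENSMUSG00000028114) lies on chromosome 3 from 123368297 to 123386108 (GRCm38). Over all cells its log2 change was -0.28 ± 0.07 (adjusted p 0.0309), in mesenchyme-like cells -0.31 ± 0.07 (0.0251) and in chondrogenic-like cells -0.22 ± 0.11 (0.159, not passing). The call over all cells was lost without cHet replicate 2 (adjusted p 0.107), cKO replicate 1 (0.118) or cKO replicate 2 (0.064). In mesenchyme-like cells it was lost without cHet replicate 1 (0.0638), cKO replicate 1 (0.0862) or cKO replicate 2 (0.07). Mettl3 did not change (0.02 ± 0.06, adjusted p 0.803). The libraries read 3' ends and the labels do not give the floxed exons, so a small change in this level neither shows nor rules out the deletion.

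Over the summed cells of each library, Runx2, Runx3 and several cartilage matrix genes were lower in cKO. Runx2 (ENSMUSG00000039153; chromosome 17, 44495987 to 44814797), a regulator of bone and late cartilage formation, fell from 60.5 ± 1.8 to 29.8 ± 4.2 CPM (mean ± SD, 2 libraries per group), a log2 change of -1.02 ± 0.10 (SE). Runx3, which acts beside Runx2 in cartilage maturation, changed by -1.50 ± 0.20, and Acan, which encodes the cartilage proteoglycan aggrecan, by -0.82 ± 0.09. Papss2, which makes the sulfate donor that cartilage proteoglycans need, fell from 56.52 ± 13.88 to 13.02 ± 1.95 CPM (-2.11 ± 0.19), and Mia, a protein secreted by cartilage cells, changed by -2.25 ± 0.13. Gdf5 (ENSMUSG00000038259; chromosome 2, 155941023 to 155945367), a growth factor of the forming joint, stood at 30.9 ± 8.7 CPM in cHet and 19.8 ± 4.5 in cKO and did not pass (-0.65 ± 0.23, adjusted p 0.0783). Gdf5 in all cells did pass without cHet replicate 2 (-0.91, adjusted p 0.00274) or without the filter on low counts (0.0444). Col2a1, the main cartilage collagen, did not pass either (-0.33 ± 0.11, adjusted p 0.0659), but Col2a1 in all cells passed with DESeq2 (0.00803), without the filter (0.0424), without cHet replicate 2 (0.00836) or without cKO replicate 2 (0.0482). Sox9, the early chondrogenic regulator, changed by -0.33 ± 0.09 and Runx1 by -0.28 ± 0.06. Sox9 in all cells lost its call without cHet replicate 1 (0.0593), cKO replicate 1 (0.134) or cKO replicate 2 (0.0952), and Runx1 in all cells without the same libraries (0.0922, 0.0722 and 0.0827). No doublet removal (0.0525) ended the Sox9 call and stricter cells (0.0693) the Runx1 call.

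**Figure D1:**
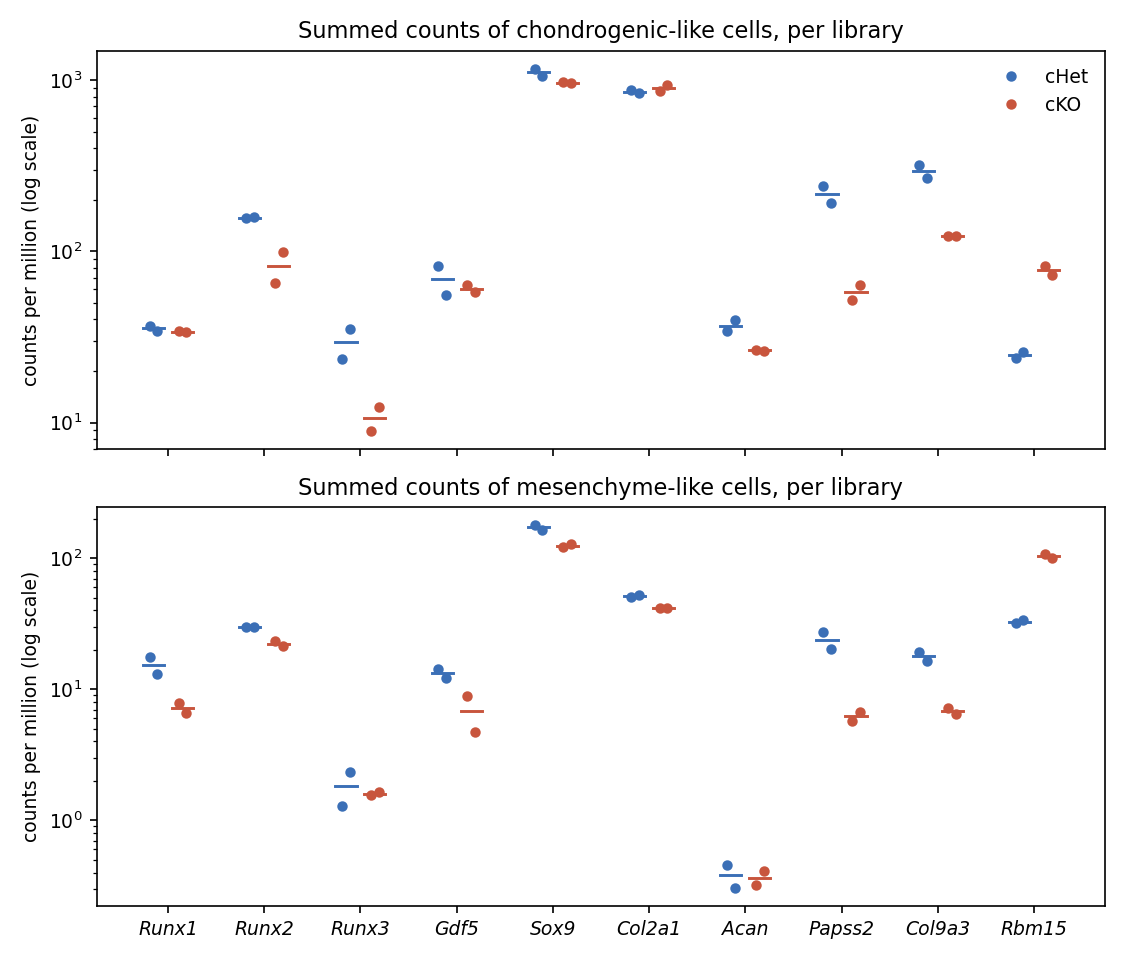
Level in CPM (log scale) of 10 named genes in chondrogenic-like and mesenchyme-like cells, with a point for each library and a bar for each group mean. In chondrogenic-like cells Runx2 went from 157 CPM in cHet to 82.1 in cKO and Papss2 from 216 to 57.5, while Col2a1 stayed near 855 and 893.

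Other large changes over all cells included rises of Rbm15, Fzd10 and Inka1 and falls of Kera and Igfbp7. Rbm15, which recruits the m6A writer complex to RNA, rose from 29.1 ± 2.4 to 85.7 ± 4.4 CPM (1.56 ± 0.07). Fzd10, a WNT receptor, rose from 20.8 to 72.1 CPM (1.79 ± 0.08) and Inka1 from 55.4 to 172 CPM (1.64 ± 0.06). Bc1, a short noncoding RNA best known from neurons, changed by 2.36 ± 0.37, Ralyl by 1.77, Pou2f2 by 1.75, Csmd3 by 1.60, Lrrc4b by 1.59, Lcmt2 by 1.58 and Prr7 by 1.48. Irx3 changed by 1.55 ± 0.31, but Irx3 in all cells lost its call without cKO replicate 1 (adjusted p 0.0642). Among the falls were Kera, a tendon and cornea proteoglycan (-1.70 ± 0.17), Apod (-1.68), Igfbp7 (-2.12), Scrn1 (-2.06), Gng3 (-1.96), Stac (-1.89), Fgf12 (-1.87) and Prtn3 (-1.78). Tpm3-rs7 (-3.16 ± 0.11) and the histone gene Hist3h2a (-1.76) may share sequence with near-identical copies, which was not checked here, so their levels are uncertain. Camk1d rose from 158 to 718 CPM (2.19 ± 0.21). edgeR called 7390 of 21645 genes at an adjusted p under 0.05, 3628 higher and 3762 lower, with 749 and 571 of them past 2-fold. Without cKO replicate 1 the count was 4247 and without cKO replicate 2 it was 4606. Cell mixture differs between the groups, so a change over all cells can come from the share of a class.

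Grouped by fixed lists, the cartilage matrix genes stood out over all cells, with 13 of 24 lower and 1 higher (Papss2, Col9a3 -1.47, Matn1 -1.77 and Hapln1 -1.01; 16 lower and 3 higher when adjusted over the list alone). Hypertrophy and growth plate genes had 6 of 11 lower, led by Ihh (-3.08), the cartilage hedgehog signal, and Fgfr3 (-0.89), the growth plate FGF receptor, and 1 higher (Pth1r 0.41). The Runx list had 3 of 4 lower, and the hedgehog list 5 of 14 lower and 1 higher (Hhip -1.56, Ptch1 -0.80, Hand2 0.47). Of the p53 targets 12 of 25 were higher and 3 lower (Aen 0.84, Ddit4l 0.93, Zmat3 0.54). Of the m6A writer genes 4 of 8 were higher and 1 lower (Rbm15, Rbm15b 0.45, Cbll1 0.34, Mettl14 -0.28). Fibrillar matrix had 10 of 28 lower and 2 higher (Dcn -1.60, Col1a2 -0.90, Col6a3 0.68), and imprinted genes 9 of 20 lower and 2 higher (H19 -0.68, Meg3 -0.67, Cdkn1c -0.52). Hypoxia and glycolysis genes had 9 of 25 lower and 1 higher (Eno1 -0.59, Slc2a1 -0.43), tendon genes 5 of 15 lower and 2 higher (Kera, Mkx -0.51), and retinoic acid genes 6 of 14 lower and 1 higher (Crabp1 -1.01, Rarg -0.25). TGF-beta genes had 6 of 16 lower (Tgfb2 -0.54, Ltbp1 -0.52) and chondrogenic transcription factors 7 of 12 lower (Barx2 -0.96, Pax9 -0.58). Histone genes had 5 of 12 higher and 1 lower (Hist1h1d 0.97, Hist1h4i 0.53), the mitochondrially encoded genes 5 of 13 higher (mt-Nd4l 0.80, mt-Nd6 0.93) and the muscle programme 8 of 26 higher (Myh3 0.61).

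These 16 of 31 lists passed with the preset correlation between genes, the cartilage matrix list at an adjusted p of 3.9e-06, the p53 list at 0.0013 and the others at 0.0023 to 0.042. None passed with the correlation estimated from the libraries (adjusted p 0.68 to 0.75 for the same lists). The cartilage matrix list did not pass with fry either (adjusted p 0.113). Both settings found it over all cells when it was planted at a 2-fold fall, larger than its median log2 change of -0.61 here. 9 lists passed without cKO replicate 2 and 10 without cKO replicate 1. The TGF-beta signalling list in all cells was lost without cHet replicate 1 (0.0925) or cKO replicate 2 (0.141), the muscle programme list in all cells without cKO replicate 2 (0.201), and the mitochondrially encoded list in all cells without the same library (0.0643). The tendon list in all cells was lost without cHet replicate 1 (0.0773), cKO replicate 1 (0.0521) or cKO replicate 2 (0.284), and the chondrogenic transcription factors list in all cells without each of the same libraries (0.0658, 0.0835 and 0.0701). The m6A writer complex list in all cells was lost without cKO replicate 1 (0.0521) or cKO replicate 2 (0.0643), and the retinoic acid list in all cells likewise (0.0521 and 0.0872). The hypoxia and glycolysis list in all cells was lost without cHet replicate 1 (0.0553) or cKO replicate 1 (0.0521), the histone genes, replication dependent list in all cells without cKO replicate 1 (0.0606) and the fibrillar and connective tissue matrix list in all cells without cKO replicate 2 (0.0643).

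The joint interzone, bone, BMP, WNT and FGF lists were among those that did not pass over all cells. The joint interzone list had 2 of 19 higher and 5 lower (Erg -0.70) and the perichondrium and osteoblast list 2 of 15 higher and 3 lower (Alpl 1.10, Runx2). BMP and GDF signalling had 5 of 30 higher and 7 lower (Bmpr1b -1.03, Bambi 0.64), WNT signalling 5 of 26 each way (Fzd7 0.52, Wnt11 -0.38) and FGF signalling 4 of 15 higher and 3 lower (Spry1 -0.62, Dusp6 0.51). The Hox A and D genes had 3 of 20 higher and 6 lower (Hoxd12 -0.84, Hoxa5 -0.73) and the limb patterning list 8 of 21 higher and 3 lower (Lhx2 0.47, Tbx5 0.33). The m6A readers and erasers had 3 of 10 higher (Ythdf2 0.81, Ythdf1 0.49, Ythdc1 0.39), where Ythdf2 encodes the reader that speeds decay of marked RNA. Interferon genes had 4 of 28 higher and 2 lower, the dissociation list 5 of 24 higher and 2 lower, the apoptosis list 4 of 18 higher and 2 lower (Bcl2 -1.08, Bax 0.32) and the integrated stress list 4 of 19 higher and 3 lower (Chac1 1.61, Slc7a11 -1.40). S phase genes had 6 of 40 higher and 10 lower and G2/M genes 13 of 52 higher and 5 lower. None of the 5 sex-linked genes passed. The adjusted p was 0.083 or above for all of these.

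In chondrogenic-like cells growth plate genes, several cartilage matrix genes, Runx2 and Runx3 fell, while Col2a1 and Sox9 did not pass. Ihh fell from 16.3 ± 3.7 to 1.77 ± 0.09 CPM (-3.20 ± 0.21), and Hapln1, which links aggrecan to hyaluronan, from 51.6 to 10.3 CPM (-2.36 ± 0.12). Papss2 (-1.90 ± 0.13), Col9a3 (-1.26 ± 0.09), the chondroitin sulfotransferase gene Chst11 (-0.92) and Acan (-0.48 ± 0.09) fell too. Runx2 fell from 157 ± 0.3 to 82.1 ± 23.6 CPM (-0.92 ± 0.16) and Runx3 from 29.4 ± 8.3 to 10.6 ± 2.5 CPM (-1.42 ± 0.22). Runx1 (-0.07 ± 0.06, adjusted p 0.453), Col2a1 (0.06 ± 0.08, 0.568), Sox9 (-0.19 ± 0.08, 0.108) and Gdf5 (-0.20 ± 0.17, 0.396) did not pass. Without cHet replicate 2 Gdf5 in chondrogenic-like cells passed (-0.45, adjusted p 0.00246), as did Sox9 in chondrogenic-like cells (-0.27, 0.0441). Without the filter on low counts both passed (0.0171 and 0.0498), and Sox9 passed with DESeq2 (0.0405) or without doublet removal (0.0345). The proximal limb regulators Meis1 and Meis2 rose from 4.8 to 30.2 CPM (2.68 ± 0.23) and from 12.9 to 61.5 CPM (2.26 ± 0.11). The distal regulator Hoxd12 (-2.38) and the patterning genes Irx2 (-4.04 ± 0.28) and Irx1 (-3.33 ± 0.31) fell, and so did Inhba (-3.08 ± 0.20) and Ptprz1 (-3.49 ± 0.37).

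Further rises in chondrogenic-like cells were Zc3hav1 (2.56 ± 0.16), an antiviral RNA-binding protein gene, Ralyl (2.67), Vwc2 (2.43), Galnt13 (2.37), Slc17a9 (2.19), Camk1d (2.13), Pou2f2 (2.05), Ptchd4 (2.03) and Rbm15 (1.64 ± 0.08). Further falls were Igfbp7 (-3.23 ± 0.11), Tpm3-rs7 (-3.05), Cntnap3 (-2.97) and Scrn1 (-2.87). edgeR called 6134 of 17081 genes, 3181 higher and 2953 lower, and 3857 without cKO replicate 1 or 3598 without cKO replicate 2. Sox9, Col2a1, Acan, Col9a genes, Hapln1 and matrilin genes are among the markers that named the class, and Hoxd12 and Meis genes are markers of mesenchyme, so their levels depend on which cells the class holds. Clusters 12 and 3 held most of the class in cHet and clusters 10 and 3 in cKO. Without cluster 12, which Papss2 led, 5051 genes were called, 4565 of them shared. Of the named genes 124 stayed on their side of the threshold, Msx2 changed sign (0.18, not passing) and 10 lost their call (Bach2, Col3a1, Col6a3, Foxc1, Hoxd13, Ror1, Skil, Slc7a5, Wnt5a and Inhba). Inhba in chondrogenic-like cells then stood at -0.42 (adjusted p 0.107), Ptprz1 in chondrogenic-like cells at -1.19, Irx1 in chondrogenic-like cells at -2.24 and Papss2 in chondrogenic-like cells at -1.12, smaller falls than with the cluster. Runx2 in chondrogenic-like cells (-1.31) and Acan in chondrogenic-like cells (-0.76) fell further without it.

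By list, most G2/M and histone genes were higher and most growth plate genes lower in chondrogenic-like cells. 10 lists passed with the preset correlation, and none with the estimated one, where their adjusted p was 0.54 to 0.78. The G2/M list had 39 of 52 higher and none lower (Birc5 1.18, Mki67 1.08; 44 higher over the list alone; adjusted p 5.6e-12), histone genes 11 of 12 higher (Hist1h2ap 1.72, Hist1h1d 1.47; 6.5e-09) and S phase genes 13 of 40 higher and 4 lower (Fen1 1.17, Exo1 1.17; 0.018). The hypertrophy and growth plate list had 9 of 11 lower (Ihh, Fgfr3 -1.02, Mef2c -1.08, Ptch1 -1.17; 2.8e-09) and the cartilage matrix list 13 of 24 lower and 3 higher (Hapln1, Papss2, Chst11; 4e-08). The hypoxia and glycolysis list had 10 of 24 lower (Pkm -0.91, Slc2a1 -0.70; 0.00065), the hedgehog list 5 of 13 lower and 2 higher (Hhip -2.23, Ptch1; 0.0075) and the retinoic acid list 5 of 12 lower (Crabp1 -0.90, Dhrs3 -0.59; 0.014). The m6A writer list had 4 of 8 higher (Rbm15, Cbll1 0.40, Virma 0.27; 0.009) and the imprinted list 6 of 20 lower and 3 higher (Cdkn1c -0.90, Snrpn -0.88; 0.031). The S phase list in chondrogenic-like cells was lost without cHet replicate 1 (0.0519) or cKO replicate 2 (0.302) and the imprinted genes list in chondrogenic-like cells without cKO replicate 1 (0.0833). The joint interzone list (4 higher and 4 lower of 19; 0.92) and the Runx list (2 of 4 lower; 0.10) did not pass. Nor did the chondrogenic transcription factors, with 5 of 12 higher and 5 lower (0.88).

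In mesenchyme-like cells Runx1, Runx2, Sox9 and Sox6 fell and Rbm15 rose. Runx1, a Runx gene active in early cartilage precursors, fell from 15.4 ± 3.3 to 7.24 ± 0.86 CPM (-1.09 ± 0.18), Runx2 from 29.9 to 22.3 CPM (-0.42 ± 0.07) and Sox9 from 172 ± 9 to 125 ± 4.6 CPM (-0.46 ± 0.07). Sox6, which works with Sox9 on cartilage genes, fell from 114 to 54.8 CPM (-1.06), and Col9a3 (-1.40) and Papss2 (-1.93 ± 0.17) fell as well. Gdf5 fell from 13.2 ± 1.4 to 6.78 ± 2.94 CPM (-0.99 ± 0.29, adjusted p 0.0488), but Gdf5 in mesenchyme-like cells lost its call without cHet replicate 1 (0.0605), with stricter cells (0.0751), at Leiden resolution 2 (0.101) or with z-scores over all cells (0.131). Col2a1 changed by -0.30 ± 0.05, and Col2a1 in mesenchyme-like cells lost its call without cKO replicate 1 (0.0649) or cKO replicate 2 (0.0535) or with those z-scores (0.0538). Runx3 (-0.18 ± 0.31, adjusted p 0.686) and Acan (-0.04, 0.939) did not pass. Fzd10 rose from 35.4 ± 1.0 to 130 ± 1.4 CPM (1.88 ± 0.05), Inka1 from 50.2 to 194 CPM (1.95 ± 0.08) and Rbm15 from 32.8 to 104 CPM (1.66 ± 0.06). Dbx2, a homeobox gene, fell from 13.1 to 1.03 CPM (-3.70 ± 0.33).

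Other rises in mesenchyme-like cells were Bc1 (2.67 ± 0.28), Dok6 (2.13), Lrrc4b (2.07), Camk1d (1.85), Csmd3 (1.82), Pou2f2 (1.78) and Cebpd (1.77). Rspo1, a WNT agonist, changed by 1.97 ± 0.34, but Rspo1 in mesenchyme-like cells lost its call without doublet removal (adjusted p 0.488) and reversed at Leiden resolution 0.5 (-0.01). Other falls were Fgf12 (-2.12), Prdm16os (-2.04), Gng3 (-2.02) and Prtn3 (-1.86), and Tpm3-rs7 (-3.29), Hist3h2a (-2.78), Hist3h2ba (-2.20) and Rbmx (-1.997). The last 4 may share sequence with near-identical copies, which was not checked here. edgeR called 6076 of 18674 genes, 3165 higher and 2911 lower, with 801 and 498 past 2-fold. Without cKO replicate 1 the count was 2880 and without cKO replicate 2 it was 3291. In both main classes 3856 genes were called, 3790 of them the same way. Both classes come from the same 4 libraries, so this overlap alone does not show a shared effect of genotype.

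The p53 target list led in mesenchyme-like cells, with 12 of 25 higher and 2 lower (Aen 1.02, Phlda3 1.14, Zmat3 0.90; adjusted p 0.00058). With the estimated correlation this list and the 4 others called in the class stood at an adjusted p of 0.95. The m6A writer list had 4 of 8 higher and 1 lower (Rbm15, Rbm15b 0.51, Cbll1 0.41; 0.0044), and the chondrogenic transcription factors 5 of 11 lower (Sox6, Sox9; 7 lower over the list alone; 0.006). Mitochondrially encoded genes had 5 of 13 higher (mt-Nd4l 0.87; 0.011) and S phase genes 16 of 40 lower and 3 higher (Nasp -0.66, Dscc1 -0.72, Fen1 1.05; 0.013). The S phase list in mesenchyme-like cells was lost without cHet replicate 1 (0.174) or cKO replicate 1 (0.0567), and the m6A writer complex list in mesenchyme-like cells without cKO replicate 1 (0.103). Cartilage matrix (6 of 23 lower and 4 higher; 0.19) and joint interzone genes (3 of 19 lower and 2 higher; 0.68) did not pass, and Ythdf2 (0.92), Ythdf1 (0.59) and Ythdc1 (0.46) rose in a reader list that did not (0.1). Lists called were 3 without cKO replicate 1 and 8 without cHet replicate 1.

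Tested gene by gene, 620 of 18435 genes changed differently in chondrogenic-like and mesenchyme-like cells, 347 with a higher and 273 with a lower change in the chondrogenic class. Runx3 had the larger fall in chondrogenic-like cells (difference -1.27 ± 0.19) and Runx1 in mesenchyme-like cells (1.04 ± 0.15). Hapln1 fell in chondrogenic-like cells and rose in mesenchyme-like cells (-2.36 and 1.07; difference -3.43 ± 0.20), and Nrg1, a growth factor gene, did the opposite (1.18 and -0.64; 1.76 ± 0.16). Ppargc1a, a regulator of mitochondrial genes, changed by -0.10 and -1.76 (1.69 ± 0.13). Sox9 differed by 0.27 ± 0.05, Irx2 by -2.96 ± 0.40, Inhba by -2.78 ± 0.35 and Dner by 1.45 ± 0.25. Gdf5 (0.90 ± 0.25, adjusted p 0.110), Runx2 (-0.50 ± 0.21, 0.239), Col2a1 (0.37 ± 0.07, 0.0502) and Acan (-0.45, 0.438) did not pass. The Gdf5 class difference passed without cHet replicate 1 (0.0181) or without the filter on low counts (0.0348), and the Col2a1 class difference passed without cHet replicate 1 (0.00631), without cHet replicate 2 (0.0321), without the filter (0.011) or with relative log expression factors (0.0489). 54 genes were called in both classes with opposite signs. The count of genes that changed differently moved widely with the library left out, so calls of single genes here are not stable. Without a cKO library the spread comes from the cHet pair alone, and without a cHet library from the cKO pair alone. Fewer calls without a cKO library therefore do not show that these genes rest on both cKO libraries.

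Interzone/perichondrium-like and tendon/connective-like cells changed as widely, with 4429 of 14735 and 6371 of 18005 genes called by edgeR. Largest were Lemd1 (4.02 ± 0.26), Bc1 (3.18) and Kcnh2 (2.75) upwards and Ppp1r14c (-3.32), Hist3h2ba (-2.91) and Tpm3-rs7 (-3.37) downwards in the first, and Lemd1 (2.99 ± 0.16), Ralyl (2.59), Csmd3 (2.54), Ano4 (-2.48), Stmn2 (-2.32) and Tpm3-rs7 (-3.10) in the second. Without cKO replicate 1 or cKO replicate 2 the counts were 2423 and 2387 in interzone/perichondrium-like cells and 3887 and 4095 in tendon/connective-like cells, where 4106 stayed without cHet replicate 1. The libraries of the 2 groups did not overlap for 70.1%, 68.5%, 70.9% and 71.1% of the tested genes in mesenchyme-like, interzone/perichondrium-like, all and chondrogenic-like cells, where chance for a single gene is 33.3%. In tendon/connective-like cells it was 71.5%. Outside the mesenchymal classes it was 48.1% in muscle-like, 43.6% in endothelium-like, 40.4% in ectoderm-like, 43.8% in macrophage-like and 27.9% in erythroid-like cells. Genes of a library move together, so any difference shared by the libraries of a group can raise these percentages. An excess over 33.3% is therefore no test of genotype.

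Cells outside the limb mesenchyme changed far less by count. Muscle-like cells had 94 of 14465 genes called (77 higher; Lrp1b 1.87 ± 0.21, Rgs6 1.55, Cthrc1 -1.06, Ntng1 -1.01), endothelium-like cells 18 of 11537 (Sema3c 2.60 ± 0.29, Naaladl2 2.20, Skap1 -5.38, Tnfaip2 -1.16) and ectoderm-like cells 23 of 12821 (Atp6v0a4 2.81 ± 0.30, Pou2f2 2.13, Fam155a -3.47, Hoxd12 -2.003). In all 3 classes Camk1d was higher (1.87, 1.89 and 1.94) and Tpm3-rs7 lower (-3.62, -2.75 and -2.79), so these 2 genes moved in whole libraries and not in a class. Without cKO replicate 1 the counts were 4, 19 and 2 and without cKO replicate 2 they were 3, 9 and 0. Apart from Tpm3-rs7 in muscle-like cells and Tpm3-rs7 and Camk1d in endothelium-like cells, each gene named here lost its call in at least 1 of these fits. Without cHet replicate 1 they were 306, 557 and 144 and without cHet replicate 2 they were 293, 220 and 15. edgeR called 0 of 5785 genes in erythroid-like cells (140 with an unadjusted p under 0.05; DESeq2 called 1) and 0 of 10999 in macrophage-like cells (1106 unadjusted; DESeq2 called 27). Olfr655 (8.33, adjusted p 0.128) and Camk1d (2.55, 0.177) had the smallest p in the first and Tpm3-rs7 (-2.59, 0.0566) and Adgrb3 (4.35, 0.0587) in the second. With a library left out, 11 to 45 genes were called in erythroid-like cells and 5 to 70 in macrophage-like cells. Summed UMIs alone do not account for the count in muscle-like cells, which held 6.63 to 14.62 M UMIs per library, near the 8.92 to 18.36 M of interzone/perichondrium-like cells with 4429 calls. Muscle-like cells were fewer, however, at 308 to 570 per library against 599 to 1026, and an effect of cell number was not tested. The other 4 classes were smaller (1.01 to 6.26 M), so a low count there does not show an absence of change.

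**Figure D2:**
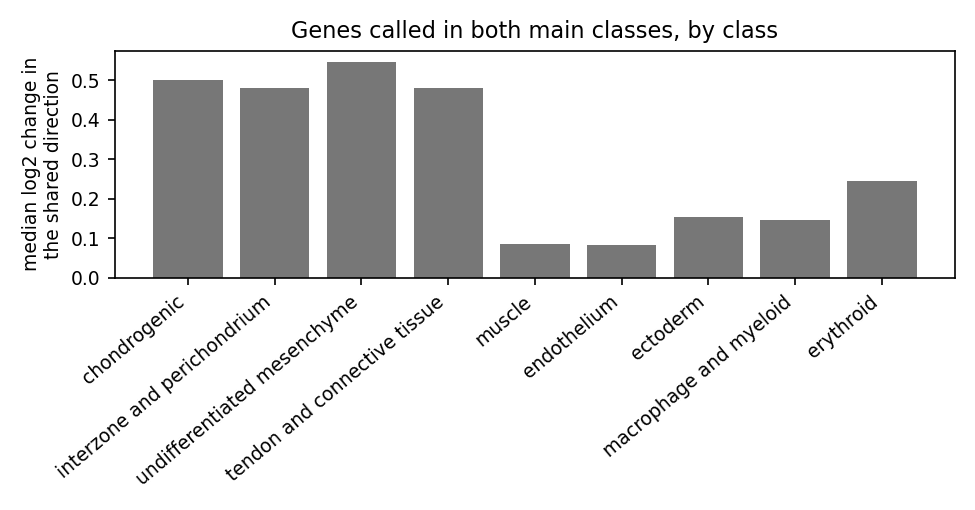
Median log2 change, in the shared direction, of the 3790 genes called the same way in chondrogenic-like and mesenchyme-like cells, as a bar for each of 9 classes. The median was 0.548 in mesenchyme-like and 0.502 in chondrogenic-like cells and 0.086 in muscle-like, 0.082 in endothelium-like and 0.246 in erythroid-like cells. The genes were chosen by their calls in the first 2 of these classes, which can raise the medians there. In interzone/perichondrium-like and tendon/connective-like cells, not used for the choice, the median was 0.481 in each.

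In mesenchyme-like cells, genes with few coding exons rose more often than genes with many. Of 1067 protein-coding genes with a single coding exon 33.5% were called higher and 9.7% lower, among them Fzd10, Lcmt2 and Cebpd higher. Of 6651 genes with 10 or more coding exons 13.7% were higher and 18.9% lower, and of those with 2 to 4 exons 26.0% and 12.2%. Across 15218 protein-coding genes the rank correlation of log2 change with exons per kb of transcript was -0.236 (bootstrap interval -0.251 to -0.22; permutation p 0.0001, the smallest possible with 10000 permutations). Genes are not independent of each other, so this p is too small. The same correlation was -0.225 in chondrogenic-like, -0.086 in muscle-like, -0.122 in endothelium-like, -0.119 in ectoderm-like, -0.132 in macrophage-like and -0.187 in erythroid-like cells.

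**Figure D3:**
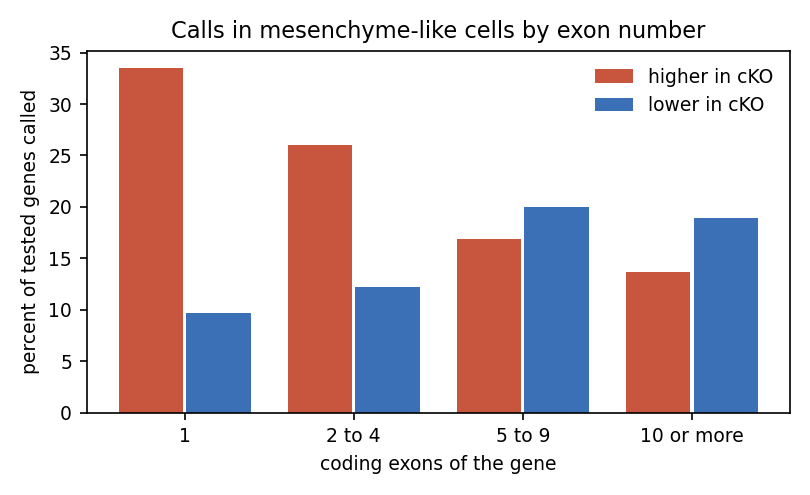
Percent of tested protein-coding genes called higher or lower in mesenchyme-like cells, as bars for genes with 1, 2 to 4, 5 to 9 and 10 or more coding exons. Calls upwards went from 33.5% to 13.7% and calls downwards from 9.7% to 18.9% over the 4 groups.

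The share of chondrogenic-like cells depended on how cells were clustered. With the called genes left out of the clustering it was 15.56% and 13.68% in cHet and 11.62% and 13.09% in cKO (log2 change -0.24 ± 0.16, adjusted p 0.271). In that clustering, however, the cluster that took up 54.7% of the cHet cells of the Papss2-led chondrogenic cluster was named mesenchyme-like, and it went from a mean of 8.67% of named cHet cells to 4.37% of named cKO cells. The smaller chondrogenic change and the larger mesenchyme change therefore depend on that name. Clustered on all variable genes it was 24.14% (95% exact binomial interval 23.42 to 24.87) and 21.35% (20.54 to 22.17) in cHet and 14.58% (13.86 to 15.32) and 16.12% (15.57 to 16.68) in cKO (-0.57 ± 0.14, 0.00349), and the call was lost without cKO replicate 1 (0.439) or cKO replicate 2 (0.237). Mesenchyme-like cells went from a mean of 37.2% to 27% without the called genes (-0.46 ± 0.07, 9.32e-06) and from 31.58% to 27.18% with them (-0.22, 0.116), where they went up among named cells alone (32.8% to 35.4%, 0.11, 0.641) and among the mesenchymal classes alone (0.127, 0.539). Tendon/connective-like cells went from 27.9% to 23.3% (-0.26 ± 0.09, 0.0346), and interzone/perichondrium-like cells stayed (6.21% and 5.83%, 0.799). Clusters that no marker set named held 4.28% and 3.3% of cHet cells and 23.55% and 22.86% of cKO cells (2.61, 6.85e-11), at median UMIs of 4252, 4797, 1988 and 3177. They take up share from every named class: among named cells alone the chondrogenic change was -0.24 (0.641). The smallest exact permutation p for 2 against 2 libraries is 0.333. All of these shares reached it apart from 3 at 0.667. These were the interzone share and the mesenchyme-like shares among named cells alone and among the mesenchymal classes alone.

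**Figure D4:**
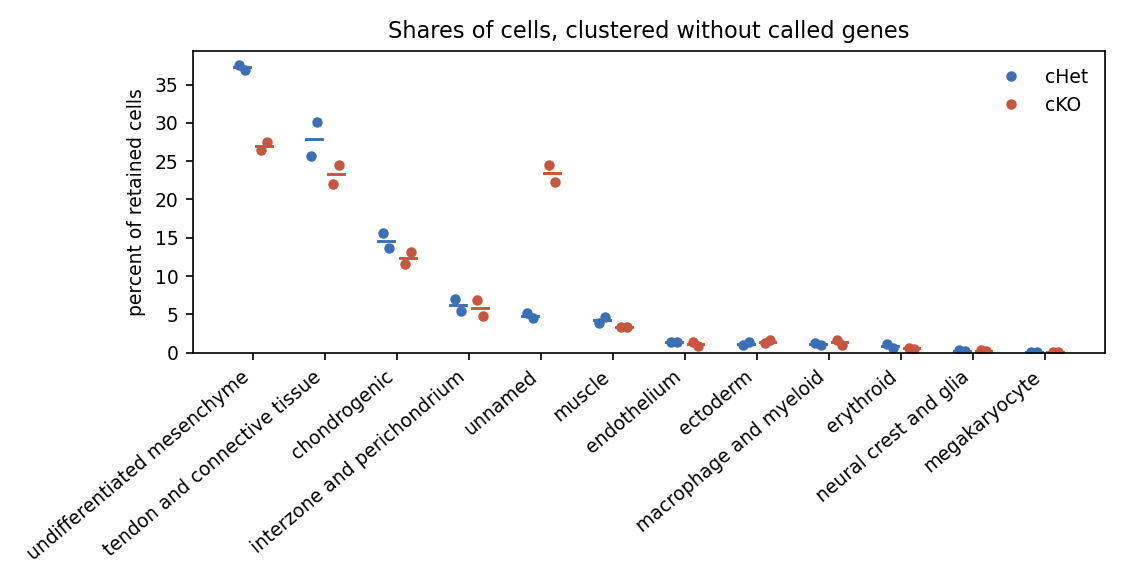
Percent of retained cells in each of 12 classes, clustered without the called genes, with a point for each library. Cells in unnamed clusters went from a mean of 4.84% in cHet to 23.4% in cKO. Mesenchyme-like cells, which here include the cluster with 54.7% of the cHet cells of the Papss2-led chondrogenic cluster, went from 37.2% to 27%.

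Single cells of the mesenchymal classes, thinned to 4000 UMIs each, held Runx transcripts less often in cKO. Runx2 was found in 11.81% (11.23 to 12.41) and 12.56% (11.87 to 13.28) of cHet cells and 7.87% (7.2 to 8.58) and 9.35% (8.83 to 9.89) of cKO cells. Gdf5 was found in 13.19% (12.58 to 13.82) and 9.62% (9.0 to 10.26) of cHet cells and 9.94% (9.19 to 10.73) and 7.61% (7.13 to 8.1) of cKO cells, so the groups overlapped. Runx1 went from 5.88% ± 0.49% to 4.24% ± 0.13%, Runx3 from 2.7% ± 0.39% to 1.12% ± 0.15% and Acan from 2.43% ± 0.13% to 1.78% ± 0.15%, while Sox9 (47.1% and 47.3%) and Col2a1 (37.27% and 35.32%) stayed. The exact permutation p was 0.333 for the 3 Runx genes and Acan, 0.667 for Gdf5 and Col2a1 and 1.0 for Sox9. Erythroid-like cells, taken as background, held Runx1 in 1.72% to 3.57%, Gdf5 in 0 to 2.38%, Runx2 in 0 to 0.66% and Runx3 or Acan in 0 to 1.19%, so the Runx3 and Acan shares lie near it. Runx1 also acts in blood cells, and in endothelium-like cells it was found in 0 to 1.74%. Before thinning, the cells kept had median UMIs of 15529, 16044, 12809 and 13805 in the mesenchymal classes and 24980, 23541.5, 21563 and 20731.5 among the erythroid-like cells. Thinning left out 101, 78, 184 and 138 cells, and unthinned the Runx2 shares were 27.9% and 20.14% and the Gdf5 shares 26.04% and 18.5%. Cells scored as G1 went from 30.52% ± 2.98% to 18.33% ± 2.9%, S from 37.16% to 43.04% and G2/M from 32.32% to 38.64% (exact permutation p 0.333). No statement on cycling is drawn from these calls alone, since an effect of free RNA on them was not tested.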

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

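The first result picked out for a closer look was that 620 genes changed by different amounts in chondrogenic-like and mesenchyme-like cells, where a shared effect of genotype would leave none past the threshold apart from false calls. The named ones were Nrg1 (difference in log2 change 1.76), Ppargc1a (1.69), Dner (1.45), Runx1 (1.04) and Sox9 (0.27) with the higher change in chondrogenic-like cells, and Hapln1 (-3.43), Irx2 (-2.96), Inhba (-2.78) and Runx3 (-1.27) with the lower. Without cKO replicate 1 or cKO replicate 2 the count was 4 and 0. Each of these genes lost its call without either cKO library, apart from Hapln1, which lost it without cKO replicate 2 alone. Both classes are sets of clusters named by markers, and Sox9 and Hapln1 are among the chondrogenic markers. Part of each difference can therefore come from which cells a class holds.

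The second was that clusters without a name held a mean of 23.2% of cKO cells against 3.79% of cHet cells. Their share was tested, but no gene test by class covers them. Their cKO cells were shallow (median UMIs 1988 and 3177) and rich in Camk1d (3819.3 and 2199.1 CPM) and in the predicted transcript Gm42418 (12769.7 and 9745.7 CPM). cKO replicate 2 supplied 1271 of the 1315 cells of cluster 14 and 523 of the 574 of cluster 18. Cluster 1, the largest, held 2043 and 2080 cKO cells among its 4960. Besides Camk1d and Gm42418, its leading genes included Ube2c, Birc5, Hist1h4d, Hist1h1b, Inka1 and Rspo1. Inka1, Rspo1 and Birc5 are also reported above as higher in named cKO classes, and whether free RNA carries them there was not tested. Camk1d and Gm42418 were also higher in named cKO cells of the mesenchymal classes (1.85 to 2.14 and 0.59 to 0.83), and by about as much in muscle-like (1.87 and 0.65), endothelium-like (1.89 and 0.63) and ectoderm-like cells (1.94 and 0.64), where Gm42418 passed in muscle-like cells alone. Of the 13 mitochondrially encoded genes 6 were called higher in chondrogenic-like cells, where the list did not pass (adjusted p 0.0514), and 5 in mesenchyme-like cells, where it did (0.011, but 0.95 with the estimated correlation). The counts over all cells hardly moved without the unnamed clusters (7383 against 7390 genes).

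2 patterns were weighed further with tests whose limits were written before their values were seen, apart from the comparison with non-mesenchymal classes, which was chosen after the result was seen. The first pattern is that 4429 to 6371 genes were called in the 4 mesenchymal classes and at most 94 elsewhere. Unequal summed UMIs of the libraries do not explain it, since 90.3% of the mesenchyme-like calls came back with sums thinned to the smallest library. That thinning acts on sums, so it does not test the lower UMIs per cell in cKO. A shift between clusters does not explain it either, since single clusters called a median of 3360 genes (1559 to 6525 over 13 clusters). A technical difference reaching every cell, such as free RNA or handling, cannot be told apart from an effect of genotype. The median change of the genes shared by the main classes, in the shared direction, was 0.168 of their mesenchymal change in muscle-like, 0.173 in endothelium-like, 0.311 in ectoderm-like and 0.318 in macrophage-like cells, the highest lying between the limits of 0.25 and 0.5 set for it. In these 4 classes 63.2% to 79.1% of the genes moved in the shared direction, and contrasts between replicates gave 0.022 to 0.056. In erythroid-like cells, which were not part of the test, the ratio was 0.589. The genes were chosen by calls that include mesenchyme-like cells, which can lower these ratios. In interzone/perichondrium-like and tendon/connective-like cells, not used for that choice, the ratio was 0.903 and 0.88.

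The second pattern is that the chondrogenic-like cluster led by Papss2 and Ptprz1 nearly vanished in cKO, with 1211 and 621 cells in cHet and 48 and 49 in cKO. A move of these cells into the unnamed low-UMI clusters is left open. Sox9, Col2a1 and Col9a1 stood there at a median of 0.115 of their level in chondrogenic-like cHet cells, but these cells would make up only a part of the unnamed clusters even if all had moved, so the limit of 0.5 could not have been reached. A relabelling, where such cells remain but their changed genes place them in other clusters, cannot be told apart from a loss of cells. Clustered without the called genes, the cluster that took up 54.7% of those cHet cells, named mesenchyme-like there, held 9.79% and 7.55% of named cHet cells and 4.23% and 4.51% of named cKO cells, a ratio of 0.504 at the limit of 0.5 set for relabelling. The chondrogenic-like cluster that took up another 30.1% of them, led by Matn4, Mia and Acan, held 6.54% and 4.79% of named cHet cells and 4.81% and 7.76% of named cKO cells, so the groups overlapped (ratio 1.109).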

How the results depend on the processing

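With 2 libraries per group, a fit with a library left out rests on a lone library assumed to vary like the others. Its spread then comes from the pair left in the other group. Over all cells, replicate counts differed more in cHet (chi-square per degree of freedom 96.3) than in cKO (22.5). That measure grows with the counts and kept the sex-linked genes, in which the cHet pair differs. Without those genes, logged CPM of the replicates correlated at 0.9937 in cHet and 0.994 in cKO over all cells. The values were 0.9925 and 0.9889 in chondrogenic-like and 0.989 and 0.9916 in mesenchyme-like cells, so neither pair was the closer one throughout. Fits with a library left out mostly called fewer genes without a cKO library. Whether this follows from the pair that sets the spread was not tested. Leaving out each library in turn gave 4247 to 6632 genes over all cells (lowest without cKO replicate 1, 4606 without cKO replicate 2), 3598 to 5331 in chondrogenic-like cells (lowest without cKO replicate 2, 3857 without cKO replicate 1) and 2880 to 6070 in mesenchyme-like cells (lowest without cKO replicate 1, 3291 without cKO replicate 2). In interzone/perichondrium-like cells it gave 2387 to 3703, in tendon/connective-like cells 3887 to 4304, in muscle-like cells 3 to 306, in endothelium-like cells 9 to 557, in ectoderm-like cells 0 to 144, in erythroid-like cells 11 to 45, in macrophage-like cells 5 to 70 and for the class difference 0 to 1821 (0 without cKO replicate 2, 1821 without cHet replicate 2). The log2 change of Mettl14 ran from -0.33 to -0.20 over all cells and from -0.35 to -0.30 in mesenchyme-like cells. The chondrogenic share change ran from -0.65 to -0.48 and the tendon share change from -0.41 to -0.36, both lost without either cKO library, and the mesenchyme share change from -0.35 to -0.0736, called without cHet replicate 1 (adjusted p 0.00902). Lists called ran from 9 to 20 over all cells, 11 to 15 in chondrogenic-like and 3 to 8 in mesenchyme-like cells.

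DESeq2 called 7113 genes over all cells (edgeR 7390), 4259 in chondrogenic-like (6134) and 5711 in mesenchyme-like cells (6076), and 2502 in interzone/perichondrium-like (4429), 219 in muscle-like (94), 63 in ectoderm-like (23), 1 in erythroid-like and 27 in macrophage-like cells (0 in both). Without the filter on low counts 1225 genes differed between the classes, against 620 with it. No list passed with the estimated correlation (0, 0 and 0 in the 3 fits), and fry called 4, 1 and 0. Over all cells fry called the m6A writer, Hox A and D, hedgehog and p53 lists (adjusted p 0.047 each). In chondrogenic-like cells it called the hypertrophy and growth plate list (0.0218). The cartilage matrix list did not pass with fry over all cells (0.113) or in chondrogenic-like cells (0.0632).

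With replicate number as a block the counts were 157 in muscle-like, 136 in endothelium-like, 370 in ectoderm-like, 1 in erythroid-like and 27 in macrophage-like cells, and 7206 over all cells. The Mettl14 change in mesenchyme-like cells (-0.31, adjusted p 0.0646) and the tendon share (-0.38) lost their calls, and the erythroid share gained one (-0.56, 0.042). Deviations from the group means of equal replicate numbers were nearly uncorrelated (0.039 over all cells, -0.193 to 0.159 elsewhere), no label pairs the libraries, and the cause was not tested. Crossing the replicate numbers called 19 genes in erythroid-like cells.

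Class shares moved with the cells and clusters used. The chondrogenic change lost its call with stricter cells (-0.40), among named cells (-0.24), among mesenchymal classes (-0.23) and clustered without called genes (-0.24). The tendon change lost it with stricter cells (-0.36), without doublet removal (-0.13), at Leiden resolution 0.5 (-0.23), among named cells (-0.0594) and among mesenchymal classes (-0.0422). The mesenchyme change gained a call without doublet removal (-0.39), at Leiden resolution 0.5 (-0.33) and 2 (-0.21) and clustered without called genes (-0.46), but was 0.11 among named cells and 0.127 among mesenchymal classes, not passing.

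Thinning depth set the size of the shares of cells with a UMI. At 2000 UMIs the difference was -0.91 percentage points for Runx1 and -0.94 for Runx3, and for S phase 3.07. Without thinning it was -7.54 for Gdf5, -6.68 for Runx1, -7.75 for Runx2, -3.2 for Runx3, -6.92 for Col2a1 and -1.75 for Acan.

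Of the alternatives for named genes 5929 gave the same call, 114 a gained call, 250 a lost call and 6 a reversed sign. The reversed ones were, at Leiden resolution 0.5, Msx2 in chondrogenic-like cells (1.21), Dlx3 in chondrogenic-like cells (0.77), Hoxd13 in chondrogenic-like cells (0.28), Fgf18 in chondrogenic-like cells (-0.21) and Rspo1 in mesenchyme-like cells (-0.00692), and Msx2 without the cluster led by Papss2 (0.18). For lists 534 gave the same call, 35 a gained and 82 a lost one.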

Other observations

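A few genes of the apoptosis and integrated stress lists changed in all 3 main fits, while the lists did not pass. Bcl2, which protects cells from death, changed by -1.08 over all cells, -1.38 in chondrogenic-like and -0.82 in mesenchyme-like cells, while Bcl2l1, which encodes a second protector, rose (0.31, 0.34 and 0.44). Slc7a11, the cystine carrier, changed by -1.40, -1.06 and -1.46 and Atf5, a stress regulator, by -0.93, -1.36 and -1.02. In mesenchyme-like cells Chac1, which breaks down glutathione, rose by 1.84, and of the interferon list Bst2 (1.88) rose while Ifit3 fell (-1.42). The apoptosis list had 2 of 18 genes higher and 2 lower there, at an adjusted p of 1.

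Single genes of other signalling lists changed in chondrogenic-like cells, in both directions. The BMP receptor gene Bmpr1b fell (-0.96; -1.06 in mesenchyme-like cells), and so did Spry1 (-1.15), an FGF antagonist, and Tgfb2 (-0.96), while the WNT receptor genes Fzd7 (0.72) and Fzd2 (0.55) rose. In mesenchyme-like cells the BMP antagonist Grem1 rose (1.13), a marker of that class. None of the BMP and GDF, FGF, TGF-beta and WNT lists passed in either class (adjusted p 0.1 to 0.92).

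Hypothesis: loss of m6A could raise transcripts with few exons, since exon junctions keep the mark away and the mark shortens the life of RNA. The limits of the tests were written before their values were seen. The rank correlation of change with exons per kb was -0.236 in mesenchyme-like cells, past the limit of -0.2. Within deciles of gene span, transcript length or level, each taken alone, it was -0.232, -0.208 and -0.248, so none of these alone took up most of it. The weakest value lies close to the limit of -0.2 and has no interval. The measures were not held together, and exons per kb itself contains transcript length, so a joint or remaining bias is not excluded. A bias of the cKO libraries that reaches every cell cannot be told apart from an effect of m6A loss, because ectoderm-like, endothelium-like and muscle-like cells held up to 0.517 of the correlation. It was -0.132 in macrophage-like and -0.187 in erythroid-like cells, which were not part of the test. Within deciles of transcript length it was -0.024 in muscle-like, -0.028 in endothelium-like, -0.016 in macrophage-like and -0.146 in ectoderm-like cells against -0.208 in mesenchyme-like cells, so outside ectoderm-like cells length takes up most of it. In endothelium-like cells the change went further with transcript length (0.273 against 0.119 in mesenchyme-like cells). A measurement of m6A or of RNA decay in sorted cells would decide it.

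Hypothesis: the higher Rbm15, Rbm15b, Cbll1, Ythdf2 and Ythdf1 levels might be a response of the m6A machinery to lower writer activity. Rbm15 and Ythdf2 rose over all cells and in both main classes, and Rbm15 lies among the genes with 2 coding exons, so the exon pattern, whose ratio reached 0.517 in the non-mesenchymal classes tested, could hold both. Whether METTL14 protein was lost was not measured here, and restoring METTL14 in cKO cells while following Rbm15 RNA decay would test it.

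Hypothesis: chondrogenic-like cells of cKO may be held at an earlier stage, with Col2a1 and Sox9 not passing, Ihh, Runx2, Runx3, Acan and Papss2 lower and cell division genes higher. The chondrogenic transcription factors were split in this class, with 5 of 12 higher and 5 lower, and their list did not pass (adjusted p 0.88). Birc5 and Ube2c, both of the G2/M list, also lead the largest unnamed low-UMI cluster, and an effect of free RNA on the cell division genes was not tested. Col2a1 and Sox9 help define the class, and Sox9 was lower in both cKO libraries and passed under 4 alternatives. For the cluster led by Papss2, the ratios of 0.504 and 1.109 in the clusters that took up 54.7% and 30.1% of its cHet cells leave open whether mature cells are missing or carry a changed profile, and without that cluster 5051 genes were still called. Cluster 10, led by Matn4, Matn1 and Acan and with Runx2 and Runx3 among its leading genes, was not smaller in cKO. It held 3.48% and 3.13% of cHet cells and 3.39% and 6.46% of cKO cells. Over all cells Gdf5 missed the threshold that the 3 Runx genes passed, but in mesenchyme-like cells Gdf5 passed and Runx3 did not, and in chondrogenic-like cells neither Gdf5 nor Runx1 passed, so an order of events between them cannot be read from these libraries. Following cartilage maturation in cKO limbs at later stages would test it.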
